A study of Mus musculus with 6 samples.

How the data were processed

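Total RNA from LSK cells of 3 WT and 3 Tet1 KO samples was measured on Affymetrix arrays, 1 array per sample, with cDNA made from 125 ng of RNA, per the labels' protocols. Samples were assigned to groups and numbered from their titles. The deposited table held log2 intensities, 1 value per probe set and array, for 45101 probe sets. The log2 scale was read from the values, which ran from 1.50 to 14.6 with near-equal medians. The method of background correction, normalization and summarization is not given in the sources used here. The probe set names are those of a 3′ whole-genome mouse array, while the labelling kits named in the labels are of the whole-transcript kind, and this was not resolved. The array medians differed by 0.0694, less than the 0.3 set as the limit for renormalizing, so the values were used as deposited. All 6 columns matched a sample.

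Probe sets were named from a platform annotation table, by which 34958 had 1 gene symbol and 932 had several. For the other 9211, which include 64 controls, no gene was listed. Only those with 1 symbol were used for genes. Of these, 34754, or 99.4%, matched a gene in a RefSeq gene table of assembly GRCm38.p6 by gene identifier, and the update changed 0 symbols. The probe set with the highest mean over all 6 arrays stood for its gene, which gave 18195 genes, of which 9011 had more than 1 probe set. No filter on dim genes was applied. As a guide to background, a bacterial control level of 4.39 was used. It is the mean over arrays of the brightest of 27 bacterial control probe sets, which do not include the hybridization controls.

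The comparison of Tet1 KO with WT was fitted in limma 3.58.1 under R 4.3.3 with lmFit and eBayes on log2 values, with genotype as the only term, two-sided, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. With 3 samples against 3, an exact permutation test of 1 gene cannot go below p = 0.1, and the limma test gains from the spread pooled over genes. Values are means ± SD of 3 arrays, and standard errors are those of the moderated fit. A descriptive count used an unadjusted p under 0.05 and at least 1.5-fold change.

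A set of 27 gene lists was written before the data were examined, along with the tests, the alternative settings and the rule for named genes. List members were matched by current symbol or by a synonym that belongs to 1 gene. The list of small nuclear and nucleolar RNA genes had 2 measured members, under the minimum of 5, and was left out. The other 26 lists were tested with camera at its preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Each list's median was also set against 10000 random lists of the same size drawn from 20 bins of mean expression. Camera compares the members of a list with all other genes, while fry tests whether the members move one way on balance.

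The rule for named genes took the 12 largest changes in each direction among genes past the adjusted threshold without overlap between groups, filled up from genes past the descriptive threshold where fewer passed. It left predicted genes, olfactory and vomeronasal receptors and small RNAs out of these 12, and added Tet1, Tet2 and Tet3 and the 4 members of each list with the smallest p. As 0 genes passed, all 12 in each direction came from the descriptive threshold.

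The fit was tested on simulated data with the means and residual spread of the 18195 genes and a known set of genes changed. It called 31.3% of 67 genes changed by 1 on the log2 scale, 76.1% of 67 genes changed by 2 and 83.3% of 66 genes changed by 3, with 8 false calls among 135. With no change simulated, 471 genes passed the descriptive threshold, 0 passed the adjusted one and 0 lists were called. The simulated genes varied independently, with equal spread on every array and no trend with level. The deposited arrays differ in these respects, so these counts are not a null for them. The shares called likewise hold only for such simulated data.

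Alternatives written in advance were quantile normalization, a shift of each array to the same median, filters on mean level, the mean of a gene's probe sets, a test of every probe set, eBayes with an intensity trend with and without robust estimation, array weights, the replicate number as a block, and leaving out each array. Cyclic loess normalization over all probe sets, the same over genes alone, and the Xist-low state of an array as a covariate were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.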

Results

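The study measured messenger RNA in LSK cells of mice that lacked Tet1 and of wild-type mice. LSK cells are bone marrow cells that carry no mature lineage markers but carry Sca-1 and Kit, and they hold the haematopoietic stem cells and the earliest multipotent progenitors. Tet1 is an enzyme that oxidises 5-methylcytosine in DNA. The title of the series treats Tet1 as a suppressor of blood cancers, and the comparison addresses which genes differ in these cells when Tet1 is missing. The cells were sorted by flow cytometry from marrow of mice at 6 months of age. There were 2 groups, WT and Tet1 KO, with 3 samples each and 1 array per sample. The labels number the samples as replicates without stating that each came from its own mouse, so p-values measure the spread between these samples. Values were log2 probe set intensities, and the array medians lay within 0.0694 of each other. The precision is limited by the 3 arrays per group.

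Tet1 itself was lower in the Tet1 KO arrays. All 4 Tet1 probe sets were lower there, and at each of the 4 every Tet1 KO array lay below every WT array. The brightest probe set read 6.81 ± 0.07 in WT and 5.80 ± 0.40 in Tet1 KO (log2, SD, n = 3 each), a difference of -1.01 with a standard error of 0.22. Its unadjusted p in limma was 0.00271, and its Benjamini-Hochberg adjusted p over all genes was 0.642. Another probe set showed a difference of -1.68, from 6.43 ± 0.24 to 4.75 ± 0.64. The position of the deleted part relative to the probe sets is not given in the sources used here, so a remaining signal does not measure functional Tet1. The related dioxygenases gave -0.19 for Tet2, with a standard error of 0.67, and -0.95 for Tet3, with a standard error of 0.46. Their unadjusted p-values in limma were 0.784 and 0.077. The Tet2 value lay between -0.81, without Tet1 KO replicate 3, and 0.63, without Tet1 KO replicate 2, and was also moved without Tet1 KO replicate 1, to -0.39, WT replicate 2, to -0.29, and WT replicate 3, to -0.10. Tet2 also gave 0.35 with array weights, -0.10 with the mean of its probe sets, -0.11 with quantile normalization and -0.09 with cyclic loess over all probe sets or over genes. Without WT replicate 3 the Tet3 value was -0.43.

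**Figure D1:**
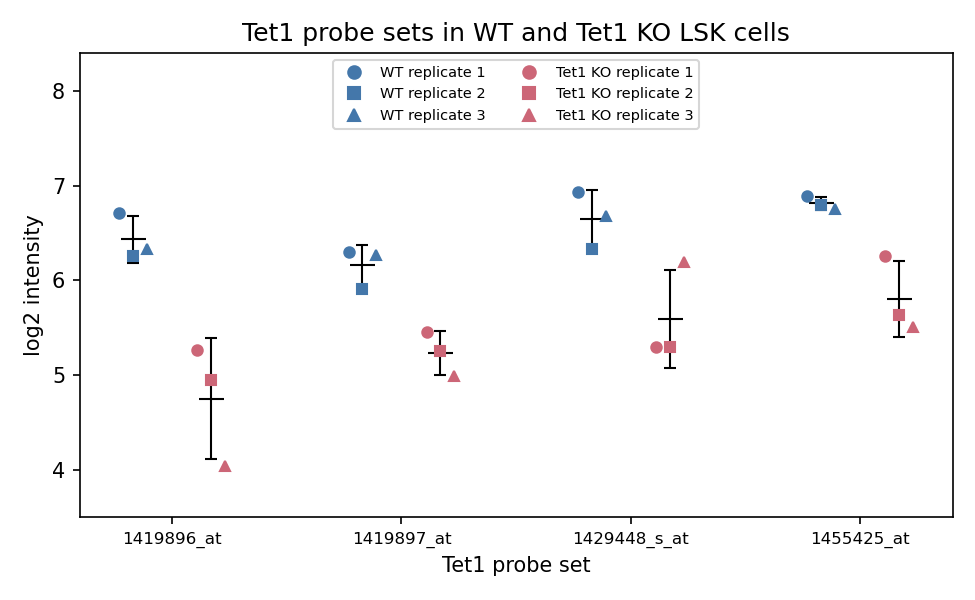
Log2 intensity of the 4 Tet1 probe sets on each array, with WT in blue, Tet1 KO in red, 1 marker shape per replicate number, and black bars for mean ± SD of 3 arrays. At each probe set the 3 Tet1 KO values lie below the 3 WT values, and at the brightest the means are 6.81 and 5.80.

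Across 18195 genes, no gene passed correction for multiple testing, and Vpreb1 and H2-Aa are given first as examples from the named genes. Vpreb1, which encodes part of the surrogate light chain of the pre-B cell receptor, read 8.28 ± 0.72 in WT and 10.01 ± 0.37 in Tet1 KO, a difference of 1.73 (SE 0.38). H2-Aa, which encodes an MHC class II chain, read 9.29 ± 0.04 in WT and 8.01 ± 0.24 in Tet1 KO, a difference of -1.28 (SE 0.17), or -0.81 with the mean of its probe sets. The number of genes with a limma Benjamini-Hochberg adjusted p under 0.05 was 0, with 0 higher and 0 lower, and the lowest adjusted p was 0.642. At an unadjusted p under 0.05 there were 1311 genes, where 909.75 are given by chance, and limma with an intensity trend gave 1419 and an adjusted count of 0. Of the 1311, 591 were higher in Tet1 KO and 720 lower. A descriptive threshold of unadjusted p under 0.05 with at least 1.5-fold change held 606 genes. In 1 simulated data set with no change and independent genes of equal spread on all arrays, 471 passed. The deposited arrays had unequal spread and a trend with level, so 471 is not a null count for them. Of the 606, 165 were higher and 441, or 72.8%, were lower. The values of both groups did not overlap for 3121 genes, or 17.2%, where chance gives 10%. Every Tet1 KO array was shifted with expression level relative to the WT mean. Such a shift can separate the groups for many genes at once. Cyclic loess, which removes such trends, left 1044 genes at an unadjusted limma p under 0.05, and 1051 when run over genes alone. Both counts are above 909.75, so part of that excess remained, with an adjusted count of 0 in both fits. Neither this excess nor that without overlap shows effects on single genes, as 0 genes passed adjustment. The count of 606 became 1327 without Tet1 KO replicate 1, with 477 higher and 850 lower, and 1055 without Tet1 KO replicate 3, with 383 higher and 672 lower, so that 64.1% and 63.7% were lower, while the adjusted count stayed at 0. The lowest adjusted p was 0.329 without Tet1 KO replicate 1, 0.135 without Tet1 KO replicate 2 and 0.0904 without Tet1 KO replicate 3. In simulated data with independent genes of equal spread on all arrays, the same test called 31.3% of 67 genes changed by 1 on the log2 scale. It called 76.1% of 67 genes changed by 2, and these shares hold only for such data.

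The largest differences without overlap between the groups were named by a rule set before the data were examined, and none of these genes passed the adjusted test. Of the 24, 10 read on average under the bacterial control level of 4.39 in at least 1 group, so background may set part of these differences: Wnk3 in both groups, Bvht and Ndrg4 in WT, and Calml4, Spaca1, Matn2, Vnn1, Tcam1, Pawr and Capsl in Tet1 KO. On the higher side, the 12 genes ran from 1.10 for Tmem181a to 2.12 for Tbce, a tubulin folding cofactor. The Tbce value had a standard error of 0.80 because its Tet1 KO arrays spread with an SD of 1.77. Hcls1, a haematopoietic adaptor of the actin cytoskeleton, differed by 1.78 (SE 0.67), and the long non-coding RNA Bvht by 1.80 (SE 0.61). Rnf170, a ubiquitin ligase of the endoplasmic reticulum, read 6.42 ± 0.16 in WT and 7.72 ± 0.42 in Tet1 KO at its brightest probe set, a difference of 1.30, while its other 2 probe sets gave -0.30 and 0.00. The other higher genes were Gprasp2, Ndrg4, Slco2b1, Slc16a9, Wnk3 and Il1rl2. Without Tet1 KO replicate 2 the values were 1.31 for Tbce, 1.02 for Hcls1, 0.82 for Gprasp2 and 0.75 for Il1rl2. Ndrg4 was at 0.87 without Tet1 KO replicate 1, and Wnk3 at 0.67 without Tet1 KO replicate 3. With the mean of probe sets instead of the brightest, Slc16a9 gave -0.03 in place of 1.24, Rnf170 gave 0.33, Ndrg4 0.68, Slco2b1 0.46 and Il1rl2 0.71. The other probe sets of Slc16a9 went the other way, at -0.88 and -0.45. On the lower side, the 12 genes ran from -2.53 for Calml4, a calmodulin-like gene, to -1.65 for Capsl. Helz2, a helicase that acts as a nuclear receptor coactivator, differed by -2.19 (SE 0.39). Zg16, a lectin of secretory granules, read 7.23 ± 0.39 in WT and 5.47 ± 0.17 in Tet1 KO. The set also held the testis genes Spaca1, at -1.94 (SE 0.33), and Tcam1, at -1.79 (SE 0.27), and the pantetheinase Vnn1, at -1.84 (SE 0.53). The rest were Matn2, Ccdc40, Aar2, Fv1 and Pawr. With the mean of probe sets the values were -0.57 for Zg16, -0.81 for Tcam1, -1.11 for Matn2, -0.52 for Aar2 and -0.75 for Pawr. The other probe sets of Tcam1, Matn2 and Pawr read under the bacterial control level in both groups, which by itself draws such a mean toward 0. Without WT replicate 3 the values were -1.50 for Calml4 and -0.98 for Aar2.

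Lymphoid genes went both ways. Of 36 measured B-lineage genes, 21 were higher and 15 lower in Tet1 KO, with 3 higher and 4 lower at an unadjusted p under 0.05. After adjustment over the list alone, 2 passed, Vpreb1 on the higher side and Cd74 on the lower side, against 0 over all genes. B-lineage genes are a theme known from the study, so this count is not independent evidence. Cd74, the invariant chain of MHC class II, read 8.76 ± 0.07 in WT and 7.54 ± 0.29 in Tet1 KO, a difference of -1.22 (SE 0.18). The transcription factor gene Lef1 differed by 1.02 (SE 0.29), and the tetraspanin gene Cd37 by -0.52 (SE 0.15), but by -0.07 with the mean of its probe sets, of which the other gave 0.38. The list was not called by camera, at an adjusted p of 0.987. Its median of 0.09 and its mean of 0.11 were positive, as was the direction from fry, while camera ranked it downward against the other genes. Among 23 genes of lymphoid-primed progenitors, 14 were higher and 9 lower, with 0 passing over the list alone and 0 over all genes, and a camera adjusted p of 0.440. Bcl11a differed by -0.44 (SE 0.20), or -0.16 with the mean of its probe sets. Rag2, of the recombinase that joins antigen receptor segments, differed by 0.67 (SE 0.28), and Ly86 by 0.99 (SE 0.50); Rag2 was at 0.45 without WT replicate 1 and Ly86 at 1.59 without Tet1 KO replicate 3. The median of this list, 0.12, stood at percentile 98.1 of random lists of matched expression. Of 19 immunoglobulin gene segments, 12 were higher and 7 lower, and Ighg3 differed by 0.36 (SE 0.14), or 0.20 with the mean of probe sets and 0.23 with cyclic loess over genes. Igkv1-117, at 0.57 (SE 0.17), read under the bacterial control level in both groups. On Tet1 KO replicate 2 the median of the B-lineage genes lay at -0.35 relative to the WT mean, against 0.08 and 0.11 on the other Tet1 KO arrays.

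Of the 29 genes of monocytes, macrophages and dendritic cells, the 4 with the smallest p were the MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 and the scavenger receptor gene Cd163. No test was made of MHC class II genes as a group. H2-Aa passed over the list alone, as 1 gene, against 0 over all genes, and gave -0.81 with the mean of its probe sets. Besides the brightest, these gave -1.42, -0.61 and 0.07, the last under the bacterial control level in both groups. H2-Ab1 differed by -0.80 (SE 0.20) and H2-Eb1 by -0.66 (SE 0.19), and each was lower on every Tet1 KO array than on any WT array. Cd163 differed by -0.71 (SE 0.20). The list as a whole had 15 members higher and 14 lower, with 11 of the 29 under the bacterial control level in both groups, and was not called, at a camera adjusted p of 0.371. Its median was 0.00046, its mean was -0.02, and camera gave it a downward direction.

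Stem cell genes fell as a list. Of 37 measured members, 30 were lower and 7 higher, with a median of -0.18, at percentile 5.33 of random lists of matched expression, and camera gave an adjusted p of 0.000429. The call was lost with an estimated correlation, at an adjusted p = 0.458 with an estimated correlation. Gfi1b, a repressor of transcription in stem cells and in the erythroid and megakaryocyte lineages, read 9.12 ± 0.14 in WT and 8.31 ± 0.12 in Tet1 KO. It was the 1 gene that passed over the list alone, against 0 over all genes. Gata2, a factor that maintains stem cells, differed by -0.66 (SE 0.25), Hlf by -0.50 (SE 0.23) and the phosphatase gene Ptpn21 by -0.59 (SE 0.24). Another Ptpn21 probe set gave -1.44 (SE 0.29), and a dimmer one, under the bacterial control level in both groups, gave 0.23. Gata2 was at -0.38 without Tet1 KO replicate 2, and without WT replicate 1 Hlf was at -0.33 and Ptpn21 at -0.39. With the mean of probe sets Gata2 was at -0.37 and Hlf at -0.29. The median relative to the WT mean was -0.18, -0.36 and -0.06 on Tet1 KO replicates 1, 2 and 3, and without replicate 2 the list call ended, at an adjusted p of 0.0825. It also ended among genes above the median level, at 0.283, with cyclic loess over genes, at 0.0664, and in fry, at 0.276.

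**Figure D2:**
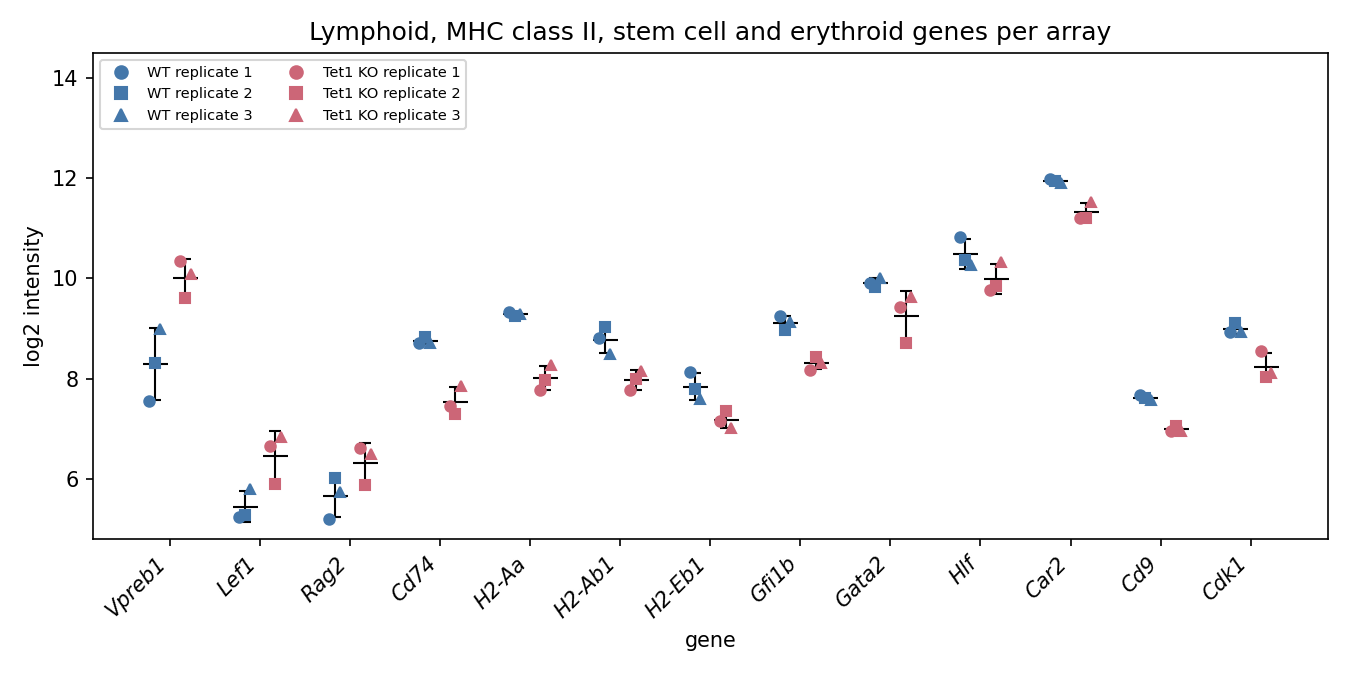
Log2 intensity of 13 named genes on each array, with WT in blue, Tet1 KO in red, 1 marker shape per replicate number, and black bars for mean ± SD of 3 arrays. Vpreb1 and Lef1 are higher on all 3 Tet1 KO arrays, Cd74 and the H2 genes are lower on all 3, and Hlf and Rag2 overlap between the groups.

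Erythroid and megakaryocyte genes were not called as lists. Of 23 erythroid genes, 14 were lower and 9 higher, with a median of -0.25, at percentile 0.06 of random lists of matched expression, and a camera adjusted p of 0.179. Gfi1b, which is also in this list, was the 1 gene that passed over the list alone, against 0 over all genes. Carbonic anhydrase 2, encoded by Car2, read 11.94 ± 0.04 in WT and 11.32 ± 0.19 in Tet1 KO, a difference of -0.62 (SE 0.15). Among 22 megakaryocyte and platelet genes, 14 were higher and 8 lower, with 0 passing over the list alone and 0 over all genes. The tetraspanin gene Cd9 differed by -0.63 (SE 0.13), from 7.62 ± 0.06 to 6.99 ± 0.05. Gp6, at 0.48 (SE 0.20) and at 0.31 with cyclic loess over genes, read under the bacterial control level in both groups. The median and the mean of this list were both 0.07 while camera ranked it downward, at an adjusted p of 0.947.

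Mast cell, basophil and eosinophil genes rose as a list relative to other genes, but 11 of 17 read on average under the bacterial control level of 4.39 in both groups. All 17 measured members were higher in Tet1 KO, with a median of 0.27, against 0.15 for random lists of matched expression, of which it stood at percentile 97.9, and a camera adjusted p of 0.0339, but 0 passed over the list alone and 0 over all genes. The call was lost with an estimated correlation, at an adjusted p = 0.594 with an estimated correlation. The shift lay on 1 array: the median of the list relative to the WT mean was 0.55 on Tet1 KO replicate 2 and 0.06 on each of the other Tet1 KO arrays. Tet1 KO replicate 2 also had the brightest bacterial control, at 4.87, against at most 4.37 on the other arrays. Without Tet1 KO replicate 2 the adjusted p was 0.288, without Tet1 KO replicate 1 it was 0.0844, and without WT replicate 1 it was 0.0890. The call also ended with quantile normalization, at 0.167, above the lower quartile of level, at 0.188, with array weights, at 0.109, with cyclic loess, at 0.303 and, over genes, 0.348, and in fry, at 0.349. Hdc, which encodes histidine decarboxylase, differed by 0.55 (SE 0.40), by 0.06 without Tet1 KO replicate 2 and by 0.23 with array weights, while the eosinophil peroxidase gene Epx, at 0.37, at 0.21 without that array and at 0.23 with cyclic loess, or 0.20 over genes, was among the 11.

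Respiratory chain genes fell as a list relative to other genes. Of 82 measured members, 66 were lower and 16 higher, with a median of -0.19, at percentile 0.1 of random lists of matched expression, and camera gave an adjusted p of 2.36e-06. The call was lost with an estimated correlation, at an adjusted p = 0.306 with an estimated correlation, and also in fry, at 0.0714, among genes above the median level, at 0.104, and with cyclic loess over genes, at 0.0900. The median relative to the WT mean was -0.18, -0.24 and -0.21 on the 3 Tet1 KO arrays. The complex I genes Ndufa9, at -0.68 (SE 0.25), Ndufa7, at -0.57 (SE 0.20), and Ndufa6, at -0.48 (SE 0.16), and the ATP synthase gene Atp5d, at -0.56 (SE 0.21), had the smallest p-values of the list, with Ndufa9 at -0.45 without Tet1 KO replicate 2 and Ndufa7 at -0.35 with the mean of its probe sets. None of these passed, with 0 over the list alone and 0 over all genes. The list was called in each of the 6 fits that left out an array. Cytosolic ribosomal protein genes had a smaller shift. Of 44 measured, 30 were lower and 14 higher, with a median of -0.08 and a camera adjusted p of 0.0223. The call was lost with an estimated correlation, at an adjusted p = 0.559 with an estimated correlation. Random lists of matched expression had a median of -0.07, and the list stood at percentile 48.6 of them. Fau, which encodes a ribosomal fusion protein, differed by -0.39 (SE 0.15) and Rpl8 by -0.29 (SE 0.13), and 0 passed over the list alone and 0 over all genes. The ribosomal call also ended without WT replicate 1, at 0.0563, without WT replicate 3, at 0.0723, without Tet1 KO replicate 1, at 0.0695, without Tet1 KO replicate 2, at 0.0825, and with the replicate number as a block, at 0.0883. It ended too with quantile normalization, at 0.149, above the lower quartile of level, at 0.224, above the median, at 0.669, with cyclic loess, at 0.552 and, over genes, 0.452, and in fry, at 0.0707.

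DNA repair genes are also a theme known from the study, so their counts are not independent evidence. Genes of base excision, nucleotide excision and mismatch repair fell as a list. Of 35 measured, 27 were lower and 8 higher, with a median of -0.17, at percentile 9.04 of random lists of matched expression, and the camera adjusted p was 0.0223. The call was lost in camera with an estimated correlation, at an adjusted p = 0.330. The estimated correlation was -0.0032, below the preset 0.01, so this loss is not evidence of correlated members. The call also ended without Tet1 KO replicate 1, at 0.0695, and without Tet1 KO replicate 2, at 0.0825. It also ended with quantile normalization, at 0.149, above the lower quartile of level, at 0.224, above the median, at 0.449, with the mean of probe sets, at 0.0537, with cyclic loess, at 0.303 and, over genes, 0.376, and in fry, at 0.197. Smug1, a uracil glycosylase gene, differed by -0.82 (SE 0.30), the mismatch repair gene Pms2 by -0.42 (SE 0.16), and the damaged DNA binding genes Ddb2 by -0.43 (SE 0.20) and Ddb1 by -0.34 (SE 0.16). Of 44 genes of homologous recombination and Fanconi anaemia, 24 were lower and 20 higher, and the camera adjusted p was 0.387. The checkpoint kinase gene Chek1 differed by 0.44 (SE 0.19), Fancc by 0.51 (SE 0.24), Mre11a by 0.69 (SE 0.33) and Bard1 by -0.48 (SE 0.24). Of 13 end joining genes, 7 were lower and 6 higher, with a camera adjusted p of 0.508. Xrcc6 differed by -0.39 (SE 0.20), and Rif1 gave 0.61 with its brightest probe set and -0.07 with the mean of its probe sets. Without Tet1 KO replicate 2 the values were -0.24 for Ddb2, 0.26 for Fancc, 0.36 for Mre11a, -0.20 for Xrcc6 and 0.33 for Rif1, and without Tet1 KO replicate 3 Bard1 was at -0.29. With the mean of probe sets Chek1 was at 0.10 and Xrcc6 at -0.08, with cyclic loess Ddb1 was at -0.21, and with array weights Fancc was at 0.34. In all 3 repair lists 0 genes passed over the list alone and 0 over all genes.

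Proliferation genes were not called as lists. Of 46 mitotic genes, 23 were higher and 23 lower, with a median of -0.01, and of 45 replication genes 22 were higher and 23 lower, with a median of -0.01. Both had a camera adjusted p of 0.347. Random lists of matched expression had lower medians, -0.12 and -0.11, and the lists stood at percentiles 98.3 and 96.9 of them. Cdk1, the mitotic kinase gene, differed by -0.76 (SE 0.18) and Birc5 by -1.32 (SE 0.56), while Bub1 gave -0.69 with its brightest probe set and 0.22 with the mean of its probe sets. Kif23 differed by 0.67 (SE 0.35), or 0.27 without Tet1 KO replicate 2, 0.39 with the mean of its probe sets and 0.41 with array weights. Among the replication genes, Tk1 differed by -0.76 (SE 0.28), Mcm10 by -0.47 (SE 0.18) and Orc1 by 0.49 (SE 0.24), or 0.26 without Tet1 KO replicate 1. Birc5 was at -0.62 without WT replicate 1, Tk1 at -0.48 without WT replicate 2 and Bub1 at -0.43 without WT replicate 3. Of 11 measured histone genes 7 were lower, and H2ac19 differed by -0.48 (SE 0.18) and H1f6 by 0.52 (SE 0.20). Of 19 telomere genes 12 were lower, and Tert, the telomerase catalytic subunit, differed by 1.08 (SE 0.37), or 0.62 with the mean of its probe sets, from a WT mean of 4.19 that lay under the bacterial control level. Terf2ip differed by -0.56 (SE 0.21), or -0.36 with the mean of its probe sets, and Nhp2 by -0.44 (SE 0.17). In these 4 lists 0 genes passed over the list alone and 0 over all genes, and the histone and telomere lists had camera adjusted p-values of 0.387 and 0.221.

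Genes of DNA methylation and of chromatin were not called as lists. Of 23 genes of DNA methylation and demethylation, 18 were lower, and the camera adjusted p was 0.179. Apart from Tet1 and Tet3, the members with the smallest p were Cxxc4, at 0.33 (SE 0.15), or 0.19 with cyclic loess and 0.16 with it over genes, and Mbd1, at -0.57 (SE 0.30). Cxxc4 read under the bacterial control level in both groups. Mbd1 was at -0.32 without Tet1 KO replicate 3 and at -0.23 with the mean of probe sets. This list was called without Tet1 KO replicate 3, at an adjusted p of 0.0163. With an estimated correlation and all arrays its camera adjusted p was 0.594. Of 32 Polycomb genes, 21 were lower, with a camera adjusted p of 0.221. Their median was -0.09, as was that of random lists of matched expression, and Bmi1, which sustains stem cell self-renewal, differed by -0.59 (SE 0.23), or -0.21 with the mean of its probe sets. Of 41 Hox genes and cofactors, 29 were higher and 12 lower, with a camera adjusted p of 0.222, and 19 read on average under the bacterial control level in both groups. Hoxa10 differed by -0.48 (SE 0.22), or -0.27 without Tet1 KO replicate 2 and -0.18 with the mean of its probe sets, and Hoxb5 by -0.49 (SE 0.23), or -0.25 without Tet1 KO replicate 3. Hoxa4 differed by 0.87 (SE 0.40), or 1.33 without Tet1 KO replicate 1 and 0.56 without Tet1 KO replicate 3, and Hoxa2 by 0.61 (SE 0.29), or 0.38 without Tet1 KO replicate 2, both from WT means under that level. In these 3 lists 0 genes passed over the list alone and 0 over all genes.

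The remaining lists held interferon, stress, p53 and other cell type genes. Of 37 interferon-stimulated genes, 20 were lower and 17 higher, with a camera adjusted p of 0.387. Usp18, a negative regulator of interferon signalling, differed by 0.88 (SE 0.20), while Ifi27l2a differed by -0.86 (SE 0.31), or -0.55 without Tet1 KO replicate 3, Ifi27 by -0.69 (SE 0.26) and Cmpk2 by -0.45 (SE 0.19). Of 30 immediate early and dissociation stress genes, 20 were higher, with a camera adjusted p of 0.289 and a median at percentile 99.9 of random lists of matched expression. The list was called among genes above the median level, at 0.0238, and with cyclic loess, at 0.0425 and, over genes, 0.0487. With an estimated correlation, on all genes and the values as deposited, its camera adjusted p was 0.690. Their median relative to the WT mean was -0.07, 0.11 and 0.54 on Tet1 KO replicates 1, 2 and 3. Without replicate 3 camera ranked them downward, at an adjusted p of 0.667. Junb differed by 0.59 (SE 0.22) and Myc by -0.38 (SE 0.20). Of 25 p53 targets, 13 were lower and 12 higher, with a camera adjusted p of 0.387, and Ak1 differed by -1.01 (SE 0.29), or -0.44 with the mean of its probe sets, Ephx1 by -0.48 (SE 0.17), both to Tet1 KO means under the bacterial control level, and Ei24 by -0.60 (SE 0.22). The mean of the p53 list was 0.03 while its median was -0.02 and camera gave it a downward direction. Of 25 T and NK cell markers 17 were higher, but 15 read on average under the bacterial control level in both groups, and Cd8a differed by 0.53 (SE 0.20), or 0.35 without Tet1 KO replicate 2 and 0.27 with the mean of its probe sets. Of 25 granulocyte genes 13 were higher, with a median at percentile 99.3 of random lists of matched expression, and Csf3r differed by 0.38 (SE 0.16). Of 20 stroma and endothelium markers 13 were higher, and Kdr differed by 0.42 (SE 0.17), or 0.26 with cyclic loess over genes, from a WT mean under that level. These 3 lists had camera adjusted p-values of 0.358, 0.528 and 0.358, and that of the immunoglobulin segments was 0.528. In these 7 lists 0 genes passed over the list alone and 0 over all genes.

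**Figure D3:**
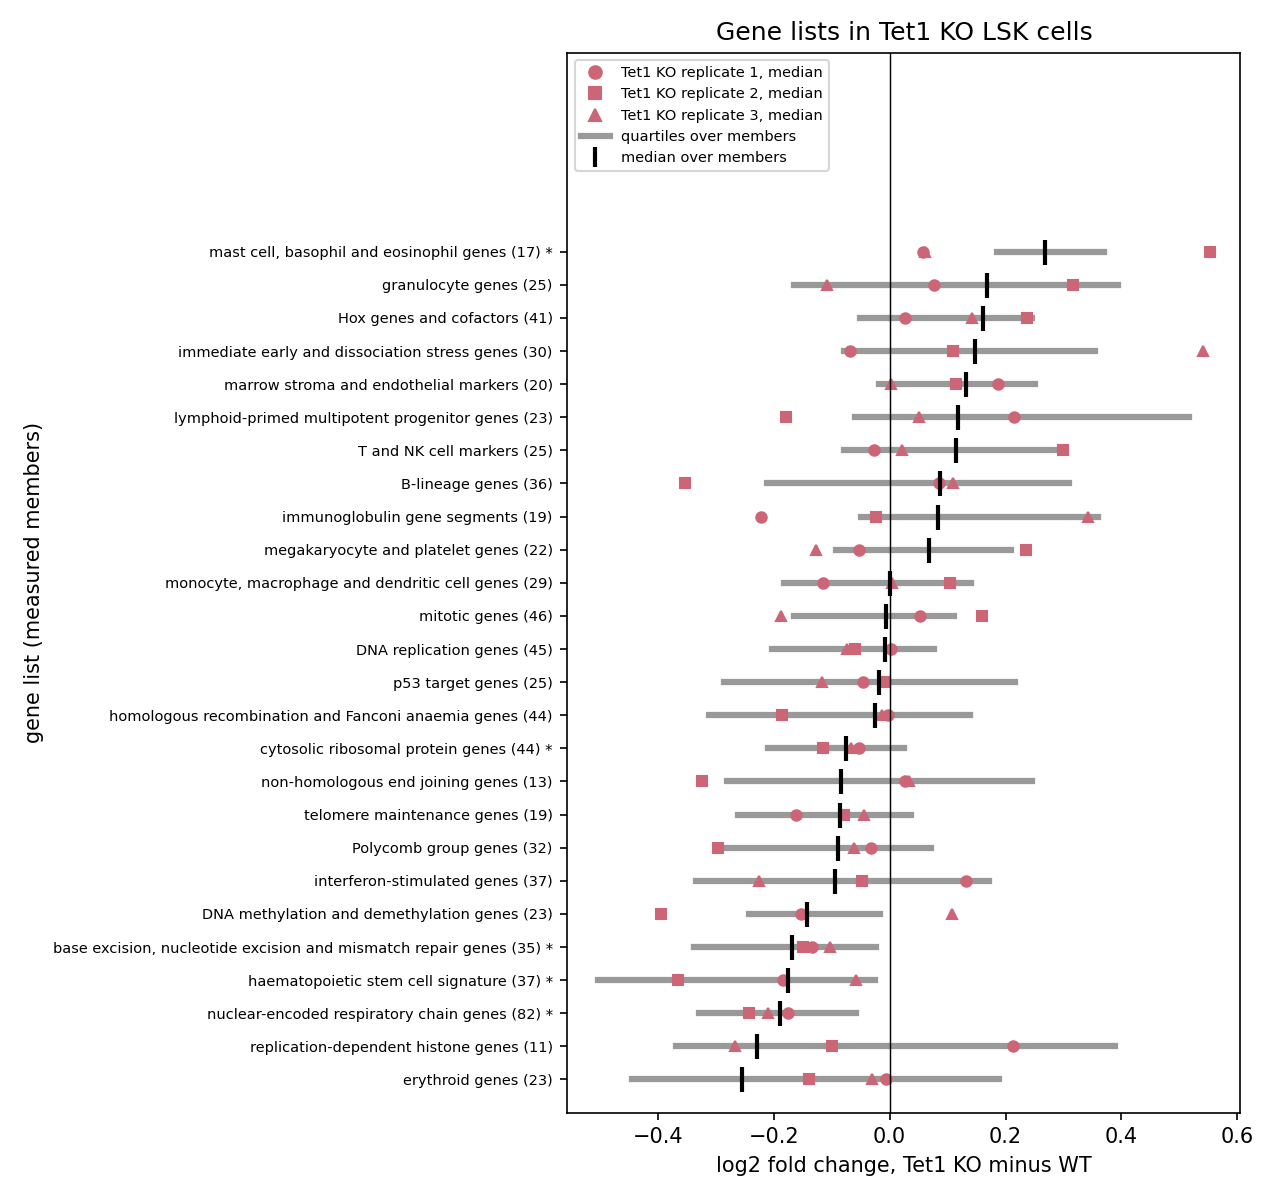
Log2 fold change of 26 gene lists in Tet1 KO against WT, with the median over members as a black mark, quartiles as a grey bar, and the median on each Tet1 KO array relative to the WT mean in red. An asterisk marks the 5 lists with a camera adjusted p under 0.05, of which 0 were called with an estimated correlation; the respiratory chain medians lie at -0.18, -0.24 and -0.21, and the mast cell shift lies on Tet1 KO replicate 2.

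Tet1 KO replicate 2 lay apart from the rest: its correlation with the other arrays over all genes ran from 0.946 to 0.951, while the other 10 pairs ran from 0.975 to 0.987. The first principal component held 47.9% of the variance and set this array against the other 5. On it 2031 genes lay more than 1 log2 unit from the median of the others, against 266 to 550 on the other arrays. Its brightest bacterial control read 4.87, against 4.21 to 4.37 on the other arrays. Xist, the RNA of the inactive X chromosome, read 4.58 on WT replicate 3 and 3.82 on Tet1 KO replicate 3, and between 11.8 and 12.2 on the other 4 arrays. The Y-linked gene Kdm5d read 8.30 and 9.16 on those arrays and at most 3.65 on the others. The labels give no sex, but by Xist and Kdm5d those arrays read as male cells and the other 4 as female cells. Each genotype held 1 such male array, so the sexes were mixed within both groups. The median log2 fold change of all genes was 0.05, and it ran from 0.18 among dim genes to -0.14 among bright genes when genes were put in 10 groups by mean level. On Tet1 KO replicate 2 this trend ran from 0.36 to -0.23 relative to the WT mean. It ran from 0.08 to -0.10 on Tet1 KO replicate 1 and from 0.10 to -0.09 on Tet1 KO replicate 3. The WT arrays lay between -0.03 and 0.04 in each group of genes. Each WT array is itself part of the WT mean, which draws its values toward 0, so the ranges of the 2 genotypes are not on an equal footing.

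**Figure D4:**
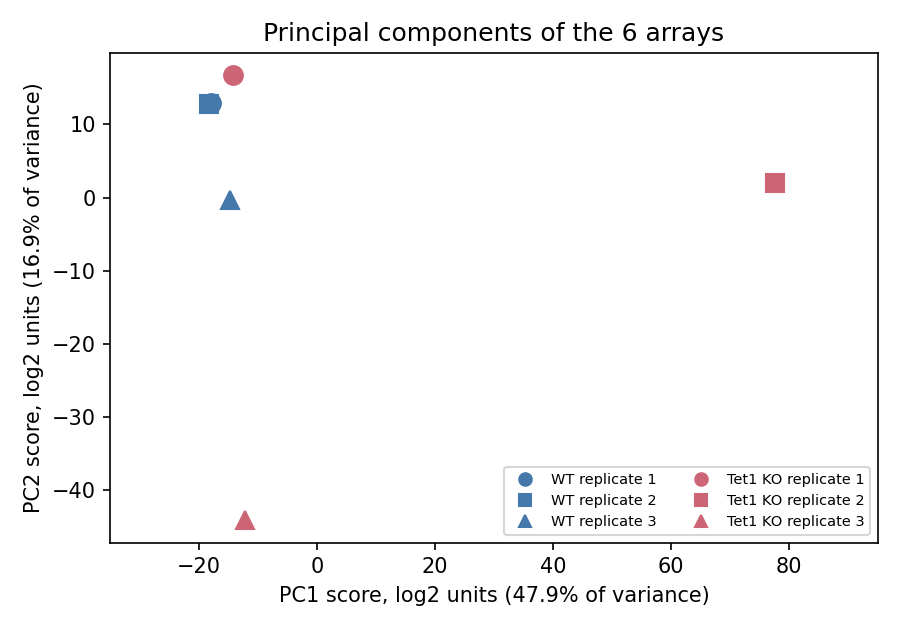
Scores of the 6 arrays on the first and second principal components of all genes, which hold 47.9% and 16.9% of the variance, with WT in blue, Tet1 KO in red and 1 marker shape per replicate number. Tet1 KO replicate 2 lies at 77.6 on the first component, and the other 5 arrays lie between -18.3 and -12.2.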

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

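The tests of hybridization controls, RNA ends, scatter on single probe sets, level trend, mature cells, chromosomes and splits were chosen only after the results were seen.

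Data outside the gene comparison held a signal in 2 places. The bacterial RNA added as a hybridization control, read by 10 probe sets, was 0.35 higher on the Tet1 KO arrays, at 10.62 ± 0.18 in WT and 10.97 ± 0.16 in Tet1 KO (exact permutation p = 0.1, the smallest p that 3 against 3 can give). A probe set with no gene listed differed by -3.34 (SE 0.21), from 6.49 ± 0.35 in WT to 3.15 ± 0.09 in Tet1 KO, with a limma Benjamini-Hochberg adjusted p of 0.0636 over all 45101 probe sets.

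Tet1 KO replicate 2 lay apart from the other 5 arrays. With labelling from the 3′ end, more degraded RNA would raise the difference of Gapdh 3′ and 5′ signal. That difference was the lowest of the 6 arrays, at -0.39 from the mean of the others. The Actb difference was also the lowest, at -0.33, against at most 0.09 on the others. The labelling kits named are of the whole-transcript kind, with which these differences may not follow degradation, so degradation stays open. Less labelled RNA would raise the hybridization controls, which read 10.995, above the 10.41, 10.71, 10.74 and 10.81 of 4 other arrays but at -0.12 from Tet1 KO replicate 3, so this stays open. Scatter of single probe sets may account for part of the distance: across 3968 genes with at least 2 probe sets, which are not independent replicates, the correlation of the deviations at 2 probe sets was 0.181 on this array and 0.189 to 0.318 on the others. The covariance of those deviations after cyclic loess was 0.113 (95% bootstrap interval 0.0869 to 0.138), higher than the 0.0259 to 0.0582 of the others, but its interval overlapped that of Tet1 KO replicate 3, which reached 0.0945. Scatter and a real difference of this sample cannot be told apart for that reason, and no biological explanation was tested.

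The shifts of 5 gene lists went with a trend of the fold change with expression level. Cyclic loess over all probe sets, which removes such trends, left 2 of the 5 lists called, and cyclic loess over genes alone left 0, as the medians moved toward 0: respiratory chain from -0.19 (quartiles -0.33 and -0.06) to -0.10 (-0.25 and 0.02), stem cell from -0.18 (-0.50 and -0.03) to -0.09 (-0.48 and -0.01), excision repair from -0.17 (-0.34 and -0.02) to -0.09 (-0.28 and 0.09), ribosomal from -0.08 (-0.21 and 0.02) to -0.03 (-0.16 and 0.07), and mast cell from 0.27 (0.18 and 0.37) to 0.13 (0.02 and 0.27). Among random lists of matched expression the ribosomal list stood at percentile 48.6, so the trend may account for its shift, while the respiratory chain stood at 0.1, stem cell at 5.33, excision repair at 9.04 and mast cell at 97.9. Such lists ignore the correlation between genes, and of 26 lists 7 lay in the outer 5%, 2 of them called. For the other 4 lists the trend and an effect of Tet1 loss cannot be told apart. Cyclic loess over genes ended the calls of all 4. Over all probe sets it ended those of excision repair and mast cell, and kept respiratory chain and stem cell, each at a camera adjusted p of 0.0425.

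H2-Aa, H2-Ab1, H2-Eb1 and Cd74, of the MHC class II pathway, were lower in Tet1 KO by 0.66 to 1.28 on the log2 scale, while among others, chosen after their values were seen, H2-DMa differed by -0.46 (SE 0.24), H2-DMb2 by 0.68 (SE 0.41) and the regulator Ciita by 0.03 (SE 0.19). A strain variant of the MHC region under the probes as the whole cause is argued against by Cd74, which lies on chromosome 18 and not on 17 and differed by -1.22 (SE 0.18). The sort removes cells with mature lineage markers, but fewer mature B cells may have passed it. Cd79b differed by -0.42 (SE 0.25) but Cd79a by 0.22 (SE 0.28). The B cell marker Ms4a1 differed by -0.03 (SE 0.17) and lay under the bacterial control level in WT, at 3.41 ± 0.23. Fewer mature B cells therefore stay open. Macrophage genes gave no common direction, as Cd163 differed by -0.71 (SE 0.20) and Lyz2 by 0.02 (SE 0.14), while C1qa, C1qb, C1qc and Vcam1 lay under the bacterial control level of 4.39 in WT, at most at 3.77 for the C1q genes, so fewer macrophages and an effect of Tet1 loss stay open. Of the dendritic cell markers, Cst3 differed by -0.19 (SE 0.31) and Siglech by 0.12 (SE 0.27). Cd209a and Itgax lay under that level in WT, so fewer dendritic cells stay open too.

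Splits of the 6 arrays into 3 against 3 number 10, too few for a share under 0.05. Genes with an adjusted p under 0.05 numbered 0 in limma, against 1311 at an unadjusted p under 0.05, and the highest other split gave 1. The descriptive count was 606 and the highest other 488. The lists called were 5 and the highest other 8.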

How the results depend on the processing

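Tests with cyclic loess, with the Xist-low state as a covariate and of array similarity were chosen only after the results were seen; the other settings were fixed before the data were examined. The count of genes with an adjusted p under 0.05 in limma was 0 under all 15 alternatives and without each array (1311 at an unadjusted p under 0.05); over every probe set 1 passed 0.1, as did 1 gene without Tet1 KO replicate 3, Bvht at 0.0904; the lowest adjusted p, 0.642 with all arrays, ran from there to 0.886 without each array. The Tet1 difference ran from -1.17 to -0.92 under alternatives and from -1.24 to -0.87 without each array. The descriptive count of 606 became 372 among genes above the median level and 126 at 2-fold, where fewer genes qualify by construction, and 1592 over every probe set, where more are tested; without each array it ran from 467 to 1327. Without Tet1 KO replicate 2 it was 651, with 330 genes shared. Of 126 named genes other than Tet1, 122 kept their direction. Many, among them the largest in each direction, had no overlap between groups, so leaving out or weighting arrays could not turn them. Several other settings leave the fold change as it is, so this count is not evidence of stability. Of 127, 59 moved by over 1.5 times without at least 1 array, 25 of them without Tet1 KO replicate 2. With the mean of probe sets 39 of 127 moved by over 1.5 times. Such a mean can take in a probe set under the bacterial control level, as for Tcam1, Pawr and H2-Aa, which lessens a difference. This count is therefore not a count of genes whose probe sets disagree. Slc16a9 turned to -0.031, Rif1 to -0.066 and Bub1 to 0.22 with the mean of probe sets, and Tet2 to 0.35 with array weights, which gave Tet1 KO replicate 2 a weight of 0.236, and without each array it ran from -0.81 to 0.63, the latter without Tet1 KO replicate 2. The highest correlation of Tet1 KO replicate 2 with another array, 0.951, became 0.857 among genes above the median level, 0.910 above the lower quartile, 0.956 with the mean of probe sets, 0.944 over every probe set, 0.955 with cyclic loess and 0.956 with cyclic loess over genes, below all other pairs each time. The lists called, 5, became 2 with quantile normalization (adjusted p: mast cell 0.167, excision repair 0.149, ribosomal 0.149), 1 among genes above the median level (stem cell 0.283, excision repair 0.449, ribosomal 0.669, respiratory chain 0.104), 2 above the lower quartile (mast cell 0.188, excision repair 0.224, ribosomal 0.224), 3 with cyclic loess (mast cell 0.303, excision repair 0.303, ribosomal 0.552), 1 with cyclic loess over genes (stem cell 0.0664, mast cell 0.348, excision repair 0.376, ribosomal 0.452, respiratory chain 0.0900), 0 with an estimated correlation (stem cell 0.458, mast cell 0.594, excision repair 0.330, ribosomal 0.559, respiratory chain 0.306) and 0 in fry (stem cell 0.276, mast cell 0.349, excision repair 0.197, ribosomal 0.0707, respiratory chain 0.0714). Excision repair was at 0.0537 with the mean of probe sets and mast cell at 0.109 with array weights. The cause was not tested. The estimated correlation was 0.021 for respiratory chain, 0.060 for stem cell, 0.055 for ribosomal and 0.186 for mast cell, above the preset 0.01. For excision repair it was -0.0032, below the preset, so the loss of that call is not evidence of correlated members. Without each array, 1 to 6 lists were called, with adjusted p from 3.70e-05 to 0.0825 for stem cell, 0.0145 to 0.288 for mast cell, 0.0145 to 0.0825 for excision repair, 0.0366 to 0.0825 for ribosomal and 5.99e-07 to 8.66e-05 for respiratory chain. The 21 other lists were called in 4 of 397 values: immediate early genes at 0.0238 above the median level, 0.0425 with cyclic loess and 0.0487 with cyclic loess over genes, and DNA methylation genes at 0.0163 without Tet1 KO replicate 3. Same-numbered arrays shared their replicate number, and the arrays numbered 3 also shared the Xist-low state. A block by number therefore also takes up that state. The deviations of arrays with the same replicate number correlated at 0.011, -0.010 and 0.025 over genes, which are not independent replicates. With that number as a block, 0 genes passed, the descriptive count was 697, the Tet1 difference -1.01, and 4 lists were called (respiratory chain 4.89e-05, stem cell 0.000554, mast cell 0.0293, excision repair 0.0293), while ribosomal was at 0.0883. Lists were not run with robust eBayes, which camera lacks, nor over every probe set. Signal over background limits genes near the bacterial control level of 4.39, where a difference may come from background; 5 of 12 mature cell markers lay above it in WT, and C1qb, at 2.93 ± 0.91, did not.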

Other observations

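The tests of germline genes and of genes beside Tet1 were chosen only after the results were seen, as were the genes named here.

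Igll1, Pou2af1 and Rag1, genes of early B cell development, read lower on Tet1 KO replicate 2 than on the other Tet1 KO arrays, but on that array 2031 genes lay over 1 log2 unit from the rest. Igll1, the partner of Vpreb1 in the surrogate light chain, read 9.002, 5.95 and 8.41 on Tet1 KO replicates 1, 2 and 3, and 6.56 ± 0.23 in WT. Pou2af1, a B cell coactivator, read 6.08, 3.46 and 5.37, and 3.62 ± 0.47 in WT. The recombinase gene Rag1 read 5.86, 2.96 and 5.52, and 4.17 ± 0.53 in WT. Pax5, which sets B cell identity, was higher on all 3, at 5.26, 5.47 and 5.19, against 4.90 ± 0.12 in WT. Without Tet1 KO replicate 2, 23 of 36 B-lineage genes and 16 of 23 lymphoid-primed progenitor genes were higher, and both lists had a camera adjusted p of 0.0825, against 0.987 and 0.440 with all arrays. No test was made of a difference between the Tet1 KO arrays.

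Testis genes were among the lower named genes, and a hypothesis was that germline genes may be lower as a class. Of 57 germline genes, 47 were higher, with a median of 0.18, near the 0.15 to 0.18 of all genes at low levels, so the count says little. Of the 23 above the bacterial control level, 15 were higher and 8 lower, with a median of 0.12 (quartiles -0.25 and 0.19), and 0.05 after cyclic loess (-0.29 and 0.13). These values argue against a lowering across these 23 genes of the size of Spaca1, at -1.94, or Tcam1, at -1.79. A small lowering of the class stays open. The camera p was 0.00209 upward, 0.236 with an estimated correlation, and 0.245 after cyclic loess.

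A segment of another strain beside the knockout allele could alter signals of genes next to Tet1. Of the 100 nearest tested genes, 10 had an unadjusted limma p under 0.05, or 10%, against 7.21% of all genes (Fisher exact one-sided p = 0.182), so the segment and chance cannot be told apart with so few genes.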
